A study of Cereibacter sphaeroides 2.4.1 with 2 samples.

How the data were processed

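RNA of the Δlov mutant (Cy3) and of the wild type 2.4.1 (Cy5) was measured on 2 two-channel Agilent arrays, 1 per replicate, both on 1 slide and from 1 scan session. Per the labels, each replicate covers 3 biological samples, RNA was isolated with hot phenol, and dye was attached directly to the RNA with a chemical labelling kit. Both arrays had the same dye orientation, with 0 dye-swapped arrays, and each array is its own pair of mutant and wild type.

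The deposited scanner files hold spot brightness as intensity, made with Agilent Feature Extraction 10.7.1.1 per the file headers: median pixel signals and local backgrounds, background-subtracted signals, and processed signals that are also dye-normalized by a linear factor and lowess. Per the file headers their log ratio is log10 of the processed Cy5 over the processed Cy3 signal. The table of the authors' own values, deposited for the whole series, is in another unit, a linear ratio: 15200 of its 15208 pairs of values matched 1 spot's ratio of background-subtracted Cy3 over Cy5 to a relative difference under 1e-05. These ratios run from mutant over wild type, are not logged and not dye-normalized, had medians of 1.08 and 2.19, and were at or below 0 for 173 and 61 spots. The submitters' processing notes name limma, and its settings are not given in the sources used here.

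Values were recomputed from the scanner files in R 4.3.3 with limma 3.58.1. The plan, made before the data were examined, called for mean signals. The files hold median signals only, so these were used with the median local backgrounds. Background was corrected with normexp (offset 50), and log ratios were normalized by loess within each array, with control spots at weight 0 and no scaling between arrays. Before loess the median log2 ratio of Cy3 over Cy5 was -0.09 on the array of replicate 1 and 0.66 on that of replicate 2. It was 0.07 and 1.19 over the dimmest 10% of spots, -0.53 and -0.18 over the brightest 10%, and -1.29 and -1.12 over the brightest 100, so that the correction moves both dim and bright features. No spot was outlier-marked or saturated. Signs were turned to mutant over wild type, spots of a probe were averaged, and then the probes of a feature. A feature was tested where at least 1 probe was well above background in at least 1 channel on both arrays, which left out 2 of 4516. A garbled prime sign in some feature names was written as '.

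The median signal was 2.83 (Cy3) and 2.59 (Cy5) times that of the negative control spots on the array of replicate 1, and 4.36 and 3.07 times on that of replicate 2. The number of arrays limits the precision. The log2 ratios were tested against 0 with limma lmFit and eBayes (two-sided, 1 residual and 6.25 prior degrees of freedom), and p-values were Benjamini-Hochberg adjusted over all 4514 features with a threshold of 0.05. The median standard error was 0.12. On simulated data of 4516 features, the test called 52.2% of features with a true log2 ratio of 0.5 and all with 1 or 2. It also called 12 of 4316 unchanged ones. The simulation left most features unchanged, gave all the same spread between arrays (SD 0.21) and held no dye bias of single features. Its shares therefore need not hold for the measured data. Calls made by the test measure the spread between the arrays and do not separate dye from genotype.

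A size rule, fixed with the plan, counted features at or beyond an absolute log2 ratio of 0.65 on both arrays. The plan also fixed which genes to name. Because the array's gene numbers are not paired with names here, only 2 numbered genes per direction are given, those with the most extreme mean log2 ratios among the called. Of non-gene features the plan allowed 4, those with the largest absolute mean past the size rule (the region IGR_0680 and antisense_RSP_0247). The other 16 past that rule, the kinds of features, the regions measured on both strands, and IGR_0019_sense and IGR_2461_2598245_2598592_sense were chosen after their values were seen. Kinds were compared with the numbered genes by Fisher's exact test, and with all other features by limma camera (preset correlation 0.01, and an estimated one). The estimated correlation rests on 1 residual degree of freedom, so that the p-values from it can decide little. The 22 gene lists of the plan, among them photosynthesis, singlet oxygen response and chaperones, had 0 members that could be matched and were not tested. The check of the deleted gene was not made for the same reason.

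The alternatives were no background correction, a normexp offset of 10, Agilent's processed signals, median centring without loess, and arrays scaled to one spread. Others were no filter or a stricter filter on dim probes, keeping outlier-marked spots, the median of probes, eBayes with an intensity trend or robust, separate channels without pairing, the deposited ratios centred on the median, a size of 1, an adjusted p of 0.1, and each array alone. A test against 0.65 with limma treat and a limit to features with at least 2 probes on the same side of 0 were added after seeing the data. A correction for probe composition was not run, since no probe sequences were used here. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.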

Results

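Transcript levels of the Δlov mutant of Rhodobacter sphaeroides (now Cereibacter sphaeroides), a purple non-sulfur bacterium that grows by photosynthesis or respiration, were compared with those of its wild type, strain 2.4.1. LOV proteins are flavin-binding receptors of blue light. Cultures of both strains started at an optical density (OD660) of 0.2 and were kept aerobic at about 170 µM oxygen. They received 0.2 µM methylene blue, a dye that passes light energy on to oxygen and so generates singlet oxygen. After a doubling in the dark they were exposed to white light of 800 W per square metre for 7 min. Total RNA of the mutant was labelled with Cy3 and that of the wild type with Cy5, and both were hybridised together to an Agilent array of DNA probes. There were 2 such arrays. Per the labels, replicate 1 held biological samples 1 to 3 and replicate 2 held biological samples 4 to 6. The dyes were not swapped between the arrays, so that in every value given here dye and genotype change together.

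Each array carried 15208 spots other than controls, with 13218 distinct probes for 4516 features. Median spot brightness on the array of replicate 1 was 4215 in Cy3 and 4190 in Cy5. On the array of replicate 2 it was 6023 in Cy3 and 2953 in Cy5. Spots well above background made up 98.9% in Cy3 and 90.9% in Cy5 on the first of these, and 99.4% and 97.5% on the second. Of the 4514 features tested, 4370 were genes that the array design lists by a number. The other 144 were named features: 107 intergenic ones whose names begin with IGR, 23 on strands opposite to genes, 11 at the flanks of genes, and 3 others (RSsh1, RSsh2 and IG-RSP0254/55). The sources used here do not pair the numbers with gene names, and 0 of the 4370 were found in the gene table used here. Genes of photosynthesis, oxidative stress defence or other pathways were therefore not grouped, and the level of the lov gene itself, which would check the strain labels, is not reported here. Among the features tested, 0 were below background in the mutant's channel on both arrays, and 5 were so in the wild type's channel. None therefore stood out as absent from the mutant alone, as a deleted gene might. This does not decide the strain labels, since 1 probe well above background on 1 array kept a feature out of the count.

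The comparison asked how the mutant and the wild type differed in transcript levels under singlet oxygen stress. Both arrays came from stressed cultures, so that a difference present without stress cannot be told apart from a changed response to it. Features of the intergenic region IGR_0680 were among the most strongly increased in the mutant. The region's 3 features, IGR_0680a_691544_692463_antisense, IGR_0680b_691544_692463_antisense and IGR_0680c_691544_692463_antisense, rose by a log2 ratio of 2.28 ± 0.28 (SD, n = 2 arrays), 2.18 ± 0.32 and 2.27 ± 0.21. In fold terms these were 4.87, 4.54 and 4.83, with limma Benjamini-Hochberg adjusted p = 0.000293, 0.000377 and 0.000256. With median centring in place of the within-array loess correction the region stood lower, at 1.30, 1.43 and 1.47 for a, b and c, and with the deposited ratios at 0.94, 1.11 and 1.14, called in both. The feature antisense_RSP_0247, on the strand opposite to a gene, rose by 1.89 ± 0.42 (adjusted p = 0.000649). Strong changes among the numbered genes went both ways. Gene 640073280 rose by 2.35 ± 0.59 and gene 640072826 by 2.25 ± 0.11, whereas gene 640071064 stood at a log2 ratio of -2.64 ± 0.30 and gene 640071063 at -2.31 ± 0.18.

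Across all features tested, 1131 (25.1%) were higher and 787 (17.4%) lower in the mutant at a limma Benjamini-Hochberg adjusted p under 0.05. Among these were 1092 higher and 766 lower of the numbered genes. Most changes were small: the median log2 ratio was 0.58 for the higher features and -0.60 for the lower, and the smallest absolute ratio called was 0.33. A log2 ratio of at least 0.65 on each array was reached by 307 features, and 234 lay at or below -0.65 on each. If the arrays were independent, 52.1 and 28.4 would be expected. No feature passed that size in opposite directions, and all 541 were called by limma. A 2-fold change on both arrays was found for 73 higher and 76 lower features. Across features, which are not independent replicates, the log2 ratios of the arrays had a Pearson correlation of 0.852 and a Spearman correlation of 0.850. The standard deviation of a feature over the arrays had a median of 0.12. When limma tested against an absolute log2 ratio of 0.65, 50 higher and 55 lower features remained past the threshold. The counts beyond 0.65 on both arrays were 95 higher and 65 lower without background correction, 561 and 376 without loess, and 865 and 562 with the deposited ratios. With only probes above background in both channels they were 248 and 261, so that the excess of higher features was lost. The counts at an adjusted p under 0.05 were 1421 higher and 1122 lower without loess, and 1532 and 1282 with the deposited ratios.

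**Figure D1:**
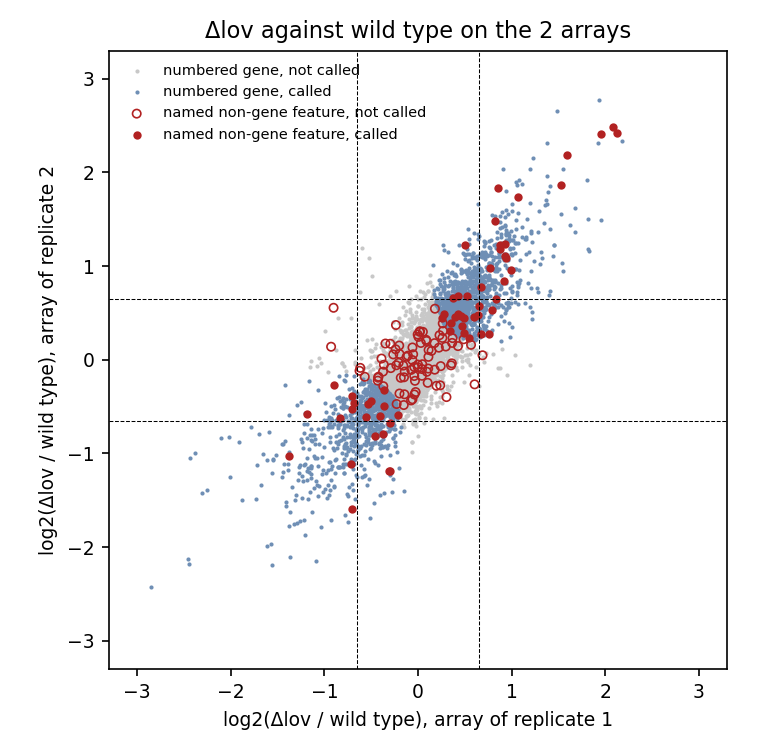
Log2 ratio of Δlov over wild type on the array of replicate 1 (horizontal) and of replicate 2 (vertical), with numbered genes as small points (blue where called by limma, grey otherwise), named non-gene features as red circles (filled where called) and dashed lines at 0.65 and -0.65. The ratios had a Pearson correlation of 0.852 across features, and no point lies beyond the lines with opposite signs.

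Gene 640073280 had 3 probes, whose mean log2 ratios ran from 1.43 to 3.10, and an adjusted p of 0.000649 in limma. Gene 640072826 (adjusted p = 0.000256) measured 2.17 and 2.33 on the separate arrays. The 3 probes of gene 640071064 (adjusted p = 0.000256) lay between -3.03 and -2.42. Those of gene 640071063, which bears the preceding number, lay between -2.52 and -1.93 (adjusted p = 0.000256). These 4 genes kept direction and call under every alternative processing that gave a test.

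Of the 144 named non-gene features, 39 were higher and 21 lower in the mutant, and the counts were equally 39 and 21 when adjusted over the list alone. With median centring in place of loess they were 22 and 82, and with the deposited ratios 19 and 93, so that the balance of this group rests on the loess correction. Beyond 0.65 on both arrays lay 17 higher, among them the 3 features of the region IGR_0680, and 3 lower. Apart from the region IGR_0680 and antisense_RSP_0247, the most strongly increased was IGR_1543_1632533_1632899_sense, at 1.70 ± 0.24 (limma adjusted p = 0.000649). Small RNAs that bear the numbers of IGR_0680, IGR_1543, IGR_0019 and IGR_2461 have been described in this species as induced by singlet oxygen, but the sources used here do not tie these probes to them. IGR_0019_sense stood at 0.38 ± 0.15 (limma adjusted p = 0.0339) and IGR_2461_2598245_2598592_sense, not called, at 0.33 ± 0.09 (adjusted p = 0.0532). With median centring they stood at -0.35 and -0.69 (adjusted p = 0.0645 and 0.00247), so that the second was called lower. With the deposited ratios they stood at -0.65 and -1.03, both called lower (adjusted p = 0.00637 and 0.000728). The first lost its call with the median of probes (adjusted p = 0.0883). The second was called higher under 4 other alternatives (adjusted p = 0.0133 to 0.0499). The intergenic features IGR_1943_2064697_2065079_antisense and IGR_0182_antisense rose by 1.41 ± 0.47 and 1.35 ± 0.70, and IGR_0234_antisense by 1.15 ± 0.47. IGR_0590_609010_609594_sense, IGR_0703_717778_717891_sense, IGR_0293_antisense and IGR_0939_974899_974972_sense rose by 0.98 to 1.08. On the strand opposite to genes, asRSP3018_No1 rose by 1.02 ± 0.12 and asRSP3793/94 by 0.73 ± 0.07. A second feature named for RSP3018, asRSP3018_No2, rose by only 0.35 ± 0.14 (limma adjusted p = 0.0462). Of the features at the flanks of genes, 3 increases went beyond that size, 3'RSP3773 at 1.01 ± 0.11, 3'RSP3796 at 0.88 ± 0.05 and 3'RSP3584 at 0.87 ± 0.15. The decreased features were IGR_0552_sense (-1.20 ± 0.25), 3'RSP6250 (-1.15 ± 0.63) and IGR_1603_1700623_1704124_sense (-0.91 ± 0.28). For the features beyond 0.65 given a value in this paragraph, limma adjusted p lay between 0.000649 and 0.00416.

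Within this group, positions are those in the feature names, in base pairs, and the replicon and genome build behind them are not given in the sources used here. The region IGR_0680 spans 691544 to 692463, IGR_1543 spans 1632533 to 1632899, IGR_1943 spans 2064697 to 2065079, and IGR_1603 spans 1700623 to 1704124. IGR_0552_sense and IGR_1603_1700623_1704124_sense rested on 2 probes each, and the other 18 on 1. Over features with 2 or more probes the SD between probes was 0.41, a spread that values from 1 probe do not show. With median centring in place of loess IGR_1543_1632533_1632899_sense stood at 0.50, IGR_1943_2064697_2065079_antisense at 0.57, IGR_0590_609010_609594_sense at 0.62, IGR_0703_717778_717891_sense at 0.40 and IGR_0939_974899_974972_sense at 0.55, all still called. With the deposited ratios, which have neither loess nor normexp and were centred on the median, IGR_1543_1632533_1632899_sense stood at 0.17 (adjusted p = 0.440), IGR_1943_2064697_2065079_antisense at 0.23, IGR_0590_609010_609594_sense at 0.37, IGR_0703_717778_717891_sense at 0.09 and IGR_0939_974899_974972_sense at 0.36, none of them called. The ratios of IGR_0293_antisense, 3'RSP3584 and asRSP3793/94 turned negative there, at -0.33, -0.39 and -0.75, and the last of these was called in that direction (adjusted p = 0.00531). IGR_0552_sense stood lower, at -2.45 without loess and -2.79 with the deposited ratios. Without background correction 3'RSP6250 stood at -0.66 and IGR_1603_1700623_1704124_sense at -0.49, both still called. With the deposited ratios IGR_0182_antisense stood at 0.54, IGR_0234_antisense at 0.75 and asRSP3018_No1 at 0.57, all still called. The feature antisense_RSP_0247 kept its call at 1.47 or more under every alternative that gave a test.

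**Figure D2:**
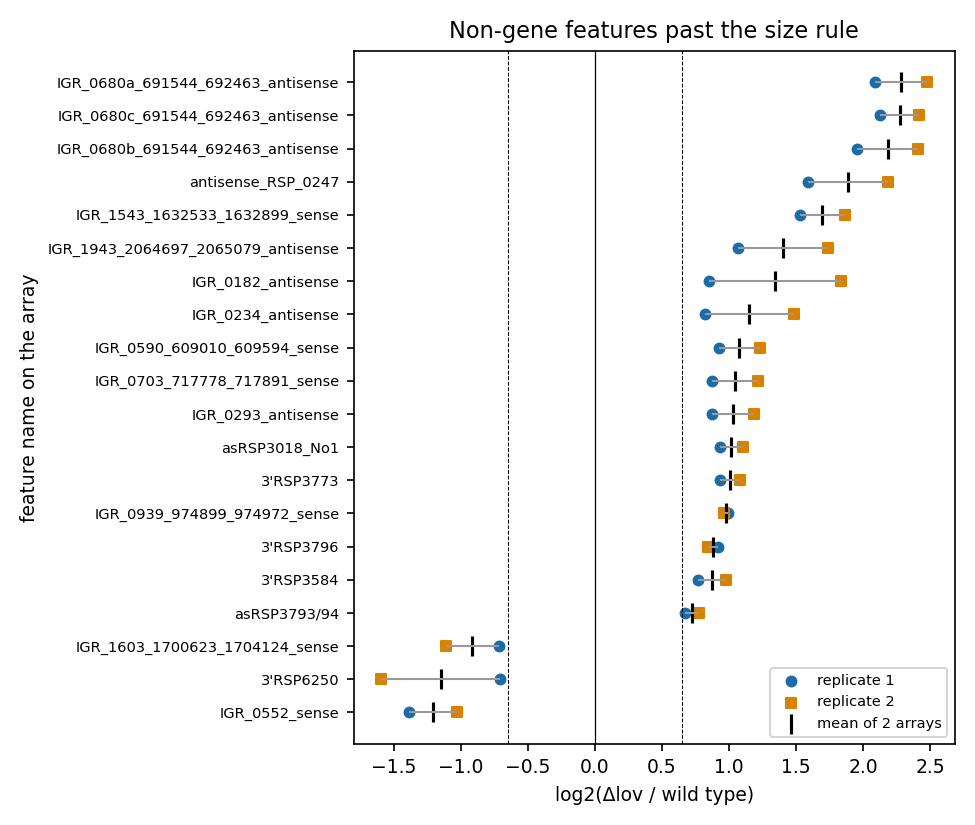
Log2 ratio of Δlov over wild type for the 20 named non-gene features beyond 0.65 (dashed lines) on both arrays (circles, replicate 1; squares, replicate 2; vertical ticks, their mean). The 3 features of the region IGR_0680 lie highest, at 2.18 to 2.28, and 3 features lie below -0.65; the directions of IGR_0293_antisense, 3'RSP3584 and asRSP3793/94 turn without the loess correction.

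Of the features on the strand opposite to a gene, 11 of 23 (47.8%) were higher and 1 lower. This share did not pass the test against the numbered genes after correction for the 8 comparisons of this family (Fisher's exact test, two-sided, p = 0.0262, adjusted p = 0.210). The limma camera test gave p = 0.0311 (adjusted p = 0.124; adjusted p = 0.690 with an estimated correlation). Their median log2 ratio was 0.33, but -0.23 with median centring in place of loess and -0.39 with the deposited ratios. Flanks of genes had 5 higher and 1 lower of 11 (median 0.36, but -0.16 with median centring and -0.42 with the deposited ratios). The region IGR_0680 counts as 3 features among the intergenic ones named antisense. Intergenic features named antisense had 12 higher and 7 lower of 48, and those named sense had 11 higher and 12 lower of 59. Their medians were -0.04 and -0.02, but -0.55 and -0.69 with median centring and -0.78 and -0.997 with the deposited ratios, where 12.5% and 5.08% were higher. The adjusted p of these 3 kinds was 0.431 or more in Fisher's exact test for higher and lower features.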

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

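The tests of the background correction and of loess, and the count of features with all probes on the same side of 0, were chosen after the data were seen, the other tests of this part before.

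Control spots for adenovirus E1A, which belong to no feature of the bacterium, gave a signal above the negative control spots in data that the comparison does not use. Over 200 such spots the median background-subtracted Cy3 signal was 335 on the array of replicate 1 and 342 on that of replicate 2, against -4.71 and -4.97 for 77 negative control spots. In Cy5 it was 485 and 312, against -99.7 and -14.5. Of the 200 spots, 195 were well above background in Cy3 on each array, but in Cy5 only 71 on the array of replicate 1 and 160 on that of replicate 2. Such signal was not particular to E1A. On the array of replicate 1 the (+)eQC control spots had medians of 278 (Cy3) and 328 (Cy5), and the ETG ones 115 and 259. The DCP ones had 54.6 and 274 there, whereas the RC ones, at 1.12 and -103, lay near the negative controls.

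A large share of features, 42.5%, was called on arrays that share a dye orientation. Dye bias of single probes as the whole cause is argued against for large changes by the features' further probes. Where the first probe of a feature lay beyond 0.65 on both arrays, a share of 0.876 of its other probes (970 of 1107, from 559 features) had its sign. Features with 1 probe are outside this test, among them those of IGR_0680, antisense_RSP_0247 and IGR_1543_1632533_1632899_sense. For features short of 0.65 on at least 1 array the test did not decide by its bounds set beforehand. There a first probe held out of the call had the sign of the call in a share of 0.8003 (934 of 1167). Its 95% binomial interval, 0.776 to 0.823, was not clearly above the 0.8 set beforehand. The interval lies wholly above the share predicted for dye bias of single probes as the whole cause. That argues against it as the whole cause for these features as a set. For part of their calls such bias stays open. Over called features of any size with 2 or more probes, 72.0% had all of them on the same side of 0 on both arrays. The background correction or loess as the whole cause is argued against as well: a share of 0.908 of the called features kept sign and call without the former and 0.831 without the latter, where 36 turned their sign (77.5% kept and 137 turned with the deposited ratios, which had no loess). Dye bias that acts on whole transcripts cannot be told apart from genotype, because the number of dye-swapped arrays is 0, and a difference between the genotypes may account for the calls only as a hypothesis beside these.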

How the results depend on the processing

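The test against 0.65 and the limit to 2 or more probes were chosen after seeing the data. Under the 13 alternatives with a test over all features, between 77.5% (deposited ratios) and 100% of the 1918 calls were kept, and 54.3% to 59.2% of calls were higher in the mutant. Of 377 tested values of the 29 named features, 355 kept direction and side of the threshold, 8 lost the call, 4 gained it and 10 reversed; their 58 values on single arrays have no test. The count of lower features became 1282 with the deposited ratios. The test against 0.65 left 50 higher and 55 lower, and the limit on probes left 711 higher and 632 lower (52.9% higher); both ask for more by construction. Features beyond 0.65 on both arrays numbered 95 higher and 65 lower without background correction, 561 and 376 without loess, 865 and 562 with the deposited ratios, and 73 and 76 at a size of 1. With only probes above background in both channels they numbered 248 higher and 261 lower, against 307 and 234 in the main setting. The calls at an adjusted p under 0.05 in limma were then 959 higher and 808 lower. Features beyond 0.65 were also counted on each array alone. On single arrays they numbered 415 to 567 and 325 to 395, where only 1 array has to pass. The correlation of the arrays, 0.852, became 0.862 without background correction, 0.862 with Agilent's processed signals, 0.864 without loess, 0.811 with the median of probes and 0.893 with the deposited ratios. IGR_0293_antisense, 3'RSP3584 and asRSP3793/94 reversed to -0.0042, -0.057 and -0.40 without loess, and to -0.33, -0.39 and -0.75 with the deposited ratios. IGR_0019_sense and IGR_2461_2598245_2598592_sense reversed to -0.35 and -0.69, and to -0.65 and -1.03. The second was called lower in both settings, the first only with the deposited ratios. Both settings leave out the loess correction, and the cause was otherwise not tested. Keeping outlier-marked spots changed nothing, as there were none. The correction for probe composition, and the estimated correlation and fry for the planned lists, were not run. Signal over the negative controls, 2.59 to 4.36 at the median spot, limits ratios of dim features, and 5 features were below background in the wild type.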

Other observations

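The regions measured on both strands were chosen after their values were seen; the tests of the last large block of numbers were also written after its result, and those on consecutive numbers before. Under a shared region name, 2 regions had a feature for each strand, and in 1 the strands moved in opposite directions. In that region, IGR_1943, IGR_1943_2064697_2065079_antisense rose by 1.41 ± 0.47 (SD, n = 2) and IGR_1943_2064697_2065079_sense fell by 0.57 ± 0.15 (limma adjusted p = 0.00129 and 0.00790), each on 1 probe. The directions held under every alternative, but with the deposited ratios neither was called, at 0.23 and -0.35 (adjusted p = 0.245 and 0.0970). Both strands of the region IGR_0422 were lower, IGR_0422_antisense at -0.58 ± 0.30 and IGR_0422_sense at -0.49 ± 0.27 (adjusted p = 0.0125 and 0.0213). They stood at -1.46 and -1.50 without loess and at -1.77 and -1.84 with the deposited ratios. IGR_0422_sense lost its call when the channels were fitted without pairing (adjusted p = 0.0698).

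Genes with consecutive numbers moved together. The log2 ratios of 4306 pairs of consecutive numbers had a correlation of 0.498 across genes. It declined to 0.387 at a distance of 2, 0.188 at 10 and 0.113 at 50. Chance order is argued against, since the highest correlation of 1000 random orders was 0.0434, and so are neighbouring spots on the array, since pairs at least 10 positions apart (3460) gave 0.495. Genes that lie side by side in the genome and are read as a unit may account for this, in part; the correlation was 0.384 higher at a distance of 1 than of 50, but no positions for the numbers were used here, which leaves it open.

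Runs of at least 4 consecutive numbers called in the same direction numbered 58 higher and 47 lower, with 331 and 301 genes. Random orders reached at most 19 and 8. The longest run of lower genes held 27, against 7 in 100 random orders, and the longest run of higher genes held 10, against 9. Across the alternatives with a test the correlation of consecutive numbers was 0.439 to 0.552.

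The last large block of numbers, which start with 640073, lay higher than other numbered genes: 197 of 488 (40.4%) were higher and 57 (11.7%) lower, with a median log2 ratio of 0.26 against 0.02. In limma camera over 11 blocks, at the preset correlation of 0.01, the adjusted p was 0.00141, and other blocks passed too. Because consecutive numbers moved together, p-values at this preset can be too small for such blocks. Block 640072 lay higher (30.4% higher, adjusted p = 0.00811), and 640069 and 640710 lay lower (28.6% and 46.7% lower, adjusted p = 0.00424 and 0.0132). None passed in limma camera with an estimated correlation, with p = 0.297 for 640073 and 0.0703, 0.0856 and 0.418 for the others in this order. That correlation was estimated from 1 residual degree of freedom, so that these p-values can decide little. Of 10000 random lists of genes matched on intensity, 0 had as high a median (highest 0.15). This gives a share of 1e-04, the smallest they can give. The lists drew scattered genes, whereas consecutive numbers moved together, and the block was picked after its value was seen. Signal level thus did not give such a median in scattered genes, but it stays open for a block of consecutive numbers. A single array as the cause is argued against, with the block 0.172 above the others on the array of replicate 1 and 0.256 on that of replicate 2. Across the alternatives with a test the block lay 0.131 to 0.529 above. What these genes have in common is not given in the sources used here, and no biological explanation was tested.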
